A study of Arabidopsis thaliana with 18 samples.

How the data were processed

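Gene expression was measured in endosperm and embryo samples of germinating Arabidopsis thaliana seeds of the accession Ler-0 (Landsberg erecta) on Affymetrix ATH1 arrays. Per the labels, seeds lay on Murashige and Skoog agar for 3 days at 4 °C and then 24 hours at 22 °C in continuous white light. The medium held no added compound, 20 µM abscisic acid (ABA, mixed isomers) or 20 µM paclobutrazol (PAC), an inhibitor of gibberellin synthesis. The 18 arrays made 6 groups of 3, taken from the tissue and treatment named in the labels. How endosperm and embryo were separated, and whether replicates came from separate cultures, is not given in the sources used here.

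The deposited values are intensity values, namely MAS5 signals on a linear scale, per the submitters' processing notes. The version of MAS5 and the detection calls are not given in the sources used here. The 2% trimmed mean of the deposited signal was 100 on each array, as read from the values, so each array had been scaled to the same mean. MAS5 subtracts mismatch signal, which makes dim probe sets noisy, and common scaling hides any difference in total RNA per tissue.

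The table held 22810 probe sets, 64 of them Affymetrix controls. The platform annotation given with the data paired 13513 probe sets with 1 gene, 503 with several and 8794 with none. Of the first, 13436 matched an entry of the TAIR10.1 gene table, which supplied symbols and loci only. They covered 13286 genes, 144 of which had more than 1 probe set. A probe set with several genes or none was tested and counted but not named, so many genes of seed biology were not analysed here by name.

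Signals were taken as log2(signal + 16), so fold changes are on that scale and understate the change of dim genes. Probe sets stayed in the test if they were no control and their mean log2 value in at least 1 group was above the 40th percentile of all values, which corresponds to a signal of 14.2. This kept 15819 probe sets, 69.6% of those that are no controls; 8757 of them had 1 gene, for 8707 genes. A linear model with a mean per group was fitted over all 18 arrays in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with trend), with 12 residual degrees of freedom. Each of 11 comparisons was adjusted by Benjamini-Hochberg, and probe sets with adjusted p under 0.05 were called. These comparisons were endosperm against embryo under each treatment, each treatment against the control in each tissue, the difference of each treatment effect between the tissues, and ABA against PAC in each tissue. The precision is limited by 3 arrays per group. The fit took 1 residual spread per probe set from all arrays, for both tissues alike. If endosperm arrays vary more than embryo arrays, endosperm p-values come out too small and embryo p-values too large.

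The genes to be named were fixed by a rule before the data were examined. For endosperm against embryo in the control and for the 4 treatment effects, the rule took the 10 genes with the largest rise and the 10 with the largest fall among called probe sets whose 3 values in one group all lay above the 3 in the other. For the tissue differences of the effects it took the 5 most positive and 5 most negative genes. Up to 4 members of each fixed gene list and 20 fixed genes were added, of which 1, ICL, had a named probe set. Genes outside the rule are said to be chosen after their values were seen.

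Of 28 lists fixed beforehand, 1 could not be built because the gene table held no descriptions. The 488 listed members had 81 named probe sets. With at least 3 tested members, 8 lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. They were LEA and dehydration proteins, gibberellin perception genes, expansins, xyloglucan endotransglucosylases, photosystem and antenna genes, Aux/IAA genes, vacuolar processing and cell death proteases, and pathogen response genes. Another 8 lists had 1 or 2 tested members and no list test, and some of these members are given as single genes. The remaining 11 had none, among them the markers of embryo, endosperm and seed coat, so that tissue purity was not tested with those markers. A further 17 lists, defined by gene family names, were added after the data were in hand and before single-gene values were looked at.

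The fit was tested on simulated data with 200 changed probe sets among 15819, far fewer than were called in these comparisons. With so few changes the adjusted threshold is stricter than in the data. Noise was drawn independently for each gene and with the same spread on every array. Shares and list calls from such data therefore do not measure recovery in the real comparisons. For the ABA effect in endosperm it recovered 8.96% of changes of 0.5 on the log2 scale, 71.6% of changes of 1 and 98.5% of changes of 2, with 9 false calls. For ABA in embryo the shares were 7.46%, 79.1% and 100%, for PAC in endosperm 5.97%, 74.6% and 98.5%, and for PAC in embryo 2.99%, 76.1% and 98.5%. For the tissues in the control they were 11.9%, 74.6% and 100%. In 100 simulations of the ABA effect in endosperm, a shift of 1 in the LEA list of 7 genes was called each time under both settings, with 7 calls (preset) and 4 (estimated) among 700 tests of unshifted lists.

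Replicate numbers in the titles were tested for pairing through the correlation of deviations from group means. Same-numbered arrays deviated together (every correlation over 0.1) between ABA and control in endosperm (0.369, 0.272 and 0.303), between ABA and control in embryo (0.124, 0.22 and 0.288) and between ABA and PAC in endosperm (0.217, 0.145 and 0.127). This pairing comes from the values, since the labels do not say what the number marks.

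Alternatives planned beforehand were pseudocounts of 1 and 64, no filter, quantile normalization, a fit on the compared arrays alone, eBayes without trend, the replicate number as a block, an estimated inter-gene correlation and each array left out in turn. Further alternatives were chosen after seeing the data. In one, the third endosperm arrays were left out together. In the others, a share f of the mean signal of the other tissue under the same treatment was subtracted from each array and the remainder divided by 1 − f. The share was first the median of the 20 lowest ratios between the tissues among probe sets with a signal of at least 1000 in the other tissue, and later also the lowest single ratio. Apart from noise no larger mean share than the lowest ratio can have been carried over in a group, so the median takes out more than the data allow. The same share was taken from each array of a group, so differences between arrays were not removed. Dimmer probe sets, with a signal of at least 200, gave lower ratios, which were not taken out in a fit here. By the same reasoning the lowest ratio used may therefore also take out more than was carried over. The division was added after the counts from subtraction alone had been seen, because subtraction without it leaves the remaining signals too low. Counts without it are given for the tissues under ABA and PAC and for the ABA effect in endosperm, and gene and list values only with it.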

Results

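The data set held 18 ATH1 arrays of germinating Ler-0 seeds, from endosperm (the thin living layer around the embryo) and embryo, each without added compound, with 20 µM ABA or with 20 µM paclobutrazol (PAC). ABA is the hormone that holds seeds back from germination, and PAC blocks gibberellin synthesis. The title of the series places its question in the transcriptomes of both tissues shortly after germination. Each group had 3 arrays. The labels do not state that replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. The median deposited signal per array lay between 22.2 and 29.2.

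Embryo and endosperm profiles were least alike in the control. The mean correlation across probe sets between arrays of the tissues was 0.767 in the control, 0.905 under ABA and 0.897 under PAC. Within embryo, ABA and PAC arrays correlated at 0.964, and each with the control at 0.826 and 0.802. The first 3 principal components held 39.4%, 34.3% and 6.45% of the variance. No arrays were near duplicates, since the closest pair, embryo PAC replicates 1 and 2, differed by 0.261 (root mean square, log2). The third endosperm array of each group stood apart, with residual SDs of 0.362 (control), 0.348 (ABA) and 0.288 (PAC) against 0.202 to 0.256 for the other endosperm arrays. Their 25S rRNA control signals were 388, 230 and 475 against 1142 to 2011 in the other endosperm arrays. Embryo arrays had 95.4 to 535, so the third endosperm arrays lay in the embryo range. In endosperm PAC replicate 3 the 3'/5' log2 ratios of GAPDH and actin were 2.47 and 6.05, and in all other arrays they were at most 1.68 and 4.79.

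**Figure D1:**
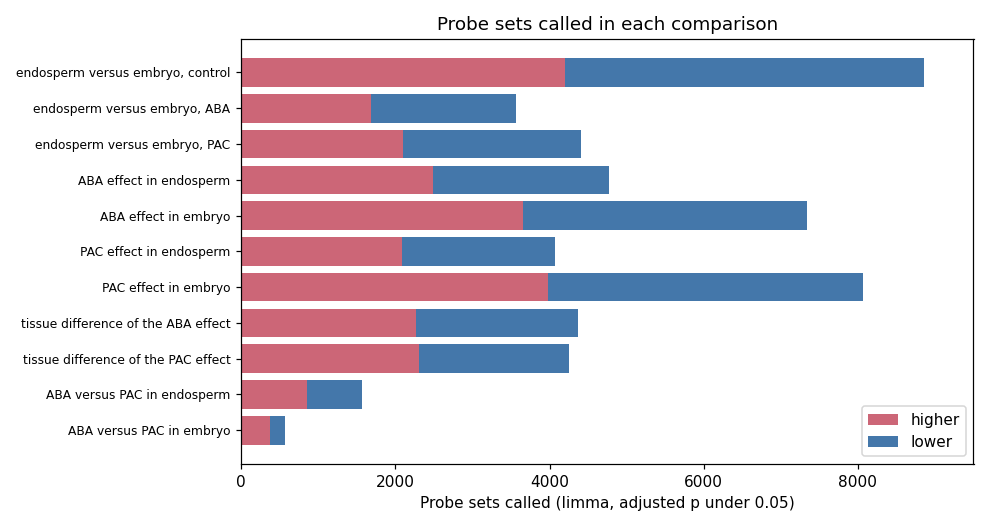
Number of probe sets called higher (red) or lower (blue) in each comparison by limma at adjusted p under 0.05, out of 15819 tested (x axis, probe sets). The bar of endosperm against embryo in the control ends at 8858 and that of ABA against PAC in embryo at 572.

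In control seeds the endosperm was marked by transcripts that were nearly dark in embryo. OCT1 (AT1G73220), an organic cation and carnitine transporter, had a mean signal of 4907 ± 930 (SD, n = 3) in endosperm and 2.49 ± 1.44 in embryo. On the log2 scale this was 8.04 ± 0.21 (SE; limma, adjusted p = 1.67e-15). The papain-type protease genes AT1G29090 and AT1G29080 were higher by 7.17 ± 0.42 and 6.49 ± 0.41, and NDB3 (AT4G21490), a mitochondrial NAD(P)H dehydrogenase, by 7.03 ± 0.36. In the other direction, the major latex protein-like gene AT4G23680 (-5.31 ± 0.22), the lectin gene JAL22 (AT2G39310; -4.69 ± 0.22), STOMAGEN (AT4G12970; -4.04 ± 0.20) and the GDSL lipase gene AT3G16370 (-4.16 ± 0.22) were lower in endosperm than in embryo.

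Vacuolar processing and cell death proteases were the fixed list with the clearest tissue difference. Of 5 tested members, 3 were higher in endosperm, 0 lower and 2 not called (4 higher when adjusted over the list alone). DELTA-VPE (AT3G20210) differed by 6.31 ± 0.16, BETA-VPE by 2.32 and GAMMA-VPE by 2.01 on the log2 scale. The list's median was 2.01 (limma camera, adjusted p = 0.0126; adjusted p = 0.0992 with an estimated correlation). LEA and dehydration proteins, which accumulate in maturing seeds, had 4 of 7 members higher in control endosperm, 0 lower and 3 not called, with the same counts when adjusted over the list alone. M17 (2.98) and M10 (2.34) were among them, and the list as a whole was not called (median 1.40, adjusted p = 0.064).

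Wall-remodelling genes were called in both directions between the tissues, as were probe sets in general, of which 56% were called in this comparison. Of 7 xyloglucan endotransglucosylases, 3 were higher in endosperm (XTH18 3.29, XTH33 2.12), 3 lower (XTH32 -2.30, XTH16 -1.58) and 1 not called. The list's median was -0.36 while its mean (0.13) and test pointed up (adjusted p = 0.991). Expansins had 3 of 11 higher, 2 lower and 6 not called, with a median of 0.28, a mean of -0.03 and an upward test (adjusted p = 0.991); when adjusted over the list alone 2 were higher and 2 lower. EXPA18 (-2.41) and EXPA7 (-2.13) were the lower ones. Pathogen response genes had 3 of 5 higher and 1 lower (median 1.65, adjusted p = 0.242), with the defensin genes PDF2.1 (3.10) and LCR67 (2.57) among the higher. For these and the following lists counts were the same when adjusted over the list alone. Photosystem genes had 1 of 10 higher and 2 lower (median -0.71, adjusted p = 0.533), Aux/IAA genes 1 of 4 higher and 2 lower (median -0.43, adjusted p = 0.533), and gibberellin perception genes 1 of 4 higher (median 0.31, adjusted p = 0.492). Without endosperm control replicate 3 the photosystem and gibberellin perception lists each had 2 higher.

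Among single genes, ICL (AT3G21720), isocitrate lyase of the glyoxylate cycle, differed by 1.13 ± 0.13, with mean signals of 7907 in endosperm and 3612 in embryo (limma, adjusted p = 8.06e-07), and PPDK, pyruvate orthophosphate dikinase, by 2.46. In all, 8858 of 15819 probe sets were called, 4200 higher and 4658 lower in endosperm, 4171 of them by at least 2-fold.

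Under ABA and PAC the tissue contrast was smaller in number. With ABA 3568 probe sets were called, 1681 higher and 1887 lower in endosperm. PAC gave 4405, with 2099 higher and 2306 lower. OCT1 remained far above embryo (7.02 ± 0.21 under ABA, 8.16 ± 0.21 under PAC), whereas M10, higher in endosperm in the control, was lower there under PAC (-1.96 ± 0.33). LEA genes had 1 of 7 higher and 3 lower under ABA (median -0.89, mean -0.13; adjusted p = 0.869; 1 lower without endosperm ABA replicate 1 or 2 or embryo ABA replicate 2 or 3), and 1 higher and 4 lower under PAC (5 lower when adjusted over the list alone; adjusted p = 0.304). No fixed list was called in either comparison. Transcripts bright in embryo were also present in the endosperm arrays of treated seeds. Among probe sets with an embryo signal of at least 1000, the 20 lowest endosperm-to-embryo ratios had a median of 29% under ABA, 20% under PAC and 5.25% in the control. The lowest single ratios were 14.2%, 11% and 1.69%, and cap the mean share carried over in a group apart from noise. At an embryo signal of at least 200 they were 13.8%, 9.23% and 0.99%, so the lowest ratios used here may also exceed the share carried over. In the other direction the medians were 0.985%, 0.703% and 0.624%. Taking out and rescaling was done with the lowest ratio at a signal of at least 1000 and with the median, which goes beyond that cap, both chosen after seeing the data. The tissue counts were 8504 and 8173 in the control, 4275 and 5218 under ABA, and 4825 and 4973 under PAC.

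The largest ABA effects in endosperm included rises of a storage protein-like and an oleosin gene and falls of a protease, a chitinase and peroxidase genes. AT4G31830 rose by 4.77 ± 0.35, the cupin storage protein-like gene AT2G28490 by 4.53 ± 0.44 and the oleosin gene AT2G25890 by 3.88 ± 0.38 (log2, n = 3). AT1G47980 rose by 3.70 ± 0.29 to a mean signal of 1271 in endosperm against 66.5 in embryo under ABA. The protease gene AT1G29090 fell by 6.74 ± 0.42 on the log2 scale, a 107-fold change (limma, adjusted p = 1.75e-09). The chitinase gene AT4G01700 (-6.34 ± 0.33) and the peroxidase genes AT5G64100 (-5.65 ± 0.29) and AT2G18980 (-4.33 ± 0.29) fell too.

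LEA genes in ABA-treated endosperm counted 5 of 7 members that rose, 1 that fell and 1 not called, the same when adjusted over the list alone. M17 rose by 2.99 and LEA4-5 by 2.88, while the dehydrin gene COR47 was at -0.68, with 0 falls without endosperm control replicate 3 or ABA replicate 2. Their median was 1.82 (limma camera, adjusted p = 0.00996; adjusted p = 0.23 with an estimated correlation). Beside this group stand the ratios above: with the lowest ratio of 14.2% taken out 3 members rose, 0 fell and the median was 1.21 (adjusted p = 0.0543), with M17 still called (2.41). With the median of 29%, beyond the cap, 2 rose, 1 fell and the median was -0.27, with M17 at -0.50 and not called. AT1G47980 (3.88 and 4.10), AT4G31830 (4.73 and 4.66) and AT2G25890 (3.94 and 4.03) still rose after either step, and of 657 probe sets that had risen at least 2-fold 594 and 454 did. Storage protein gene PAP85 rose by 2.88 as deposited and was not called after either step (2.11 and -1.76).

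Among wall genes, 4 of 7 xyloglucan endotransglucosylases fell under ABA in endosperm, 0 rose and 3 were not called (the same when adjusted over the list alone), led by XTH18 (-3.29) and XTH33 (-1.93). The median was -1.14 (limma camera, adjusted p = 0.00043; adjusted p = 0.106 with an estimated correlation), and with 4 falls it was -1.25 after the lowest ratio and -1.15 after the median ratio was taken out. Expansins had 3 of 11 that fell, 0 that rose and 8 not called (1 rose when adjusted over the list alone), with a median of -0.01 (limma camera, adjusted p = 0.572). With the lowest embryo ratio taken out 2 fell, with the median ratio 1 fell, and 1 rose after either step. Only 1 expansin fell without endosperm control replicate 1 or 2 or ABA replicate 1 or 2, and 1 rose without control replicate 1 or ABA replicate 2 or 3. Vacuolar proteases had 3 of 5 that fell and 1 that rose (median -0.89, adjusted p = 0.0912). DELTA-VPE was at -0.89, and GAMMA-VPE at -1.15, or -0.59 without endosperm control replicate 3, while BETA-VPE rose by 0.82. Of 5 pathogen response genes 3 rose and 0 fell (1 fell when adjusted over the list alone), with PDF2.1 up by 2.68. Their list median was 1.16 (limma camera, adjusted p = 0.0445; adjusted p = 0.23 with an estimated correlation). This list call also ended without endosperm control replicate 1 (median 1.35), ABA replicate 2 (1.18) or ABA replicate 3 (1.13), and without the third endosperm arrays (0.85). It ended as well with the lowest (1.08) or median (0.94) embryo ratio taken out, at pseudocount 1 (1.35) and with quantile normalization (1.14). Photosystem genes had 1 of 10 that rose and 2 that fell (median -0.24, adjusted p = 0.502). Of these, 0 rose without endosperm control replicate 1 or 2 or ABA replicate 1 or 2 and 2 rose without ABA replicate 3, while 1 fell without control replicate 3 or ABA replicate 3. Gibberellin perception genes had 1 of 4 that rose and 1 that fell, SPT, a bHLH transcription factor, at -1.43; the list median was -0.23 (adjusted p = 0.572), and 0 rose without endosperm control replicate 2 or 3 or ABA replicate 1. Among 4 Aux/IAA genes 1 fell, with a median of 0.01, a mean of -0.20 and a downward test (adjusted p = 0.572), and 1 rose without endosperm control replicate 1 or ABA replicate 3.

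ABA changed 4778 probe sets in endosperm, 2485 up and 2293 down. A fit on these 6 arrays alone called 2370, and one without the third endosperm arrays 4319. With the lowest embryo ratio taken out 3939 were called (4027 without rescaling), and with the median ratio 3249 (4734 without rescaling).

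The largest ABA effects in embryo included rises of M17, of defensin genes and of a storage protein gene, and a fall of PORB. M17 (AT2G41260) rose by 7.43 ± 0.46 from a mean signal of 12.9 to 4771 (limma, adjusted p = 2.77e-10). PDF2.1 rose by 6.26 ± 0.32, M10 by 6.16 ± 0.33 and PAP85, a vicilin-like storage protein gene, by 6.10 ± 0.45 (n = 3). AT4G23680 (-5.98 ± 0.22), the lipid transfer-like gene AT2G45180 (-5.08 ± 0.60) and PORB (AT4G27440; -4.84 ± 0.42), protochlorophyllide oxidoreductase of chlorophyll synthesis, fell.

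Of 7 LEA genes 5 rose, 1 fell (COR47, -3.15) and 1 was not called in ABA-treated embryo (median 3.58; limma camera, adjusted p = 0.00416; adjusted p = 0.178 with an estimated correlation). Pathogen response genes had 3 of 5 that rose and 1 that fell (median 3.14, adjusted p = 0.00416; adjusted p = 0.178 with an estimated correlation). Xyloglucan endotransglucosylases fell in 6 of 7 cases, XTH32 at -2.44 and XTH16 at -1.47, for a median of -1.47 (adjusted p = 0.00178; adjusted p = 0.169 with an estimated correlation). Expansins had 4 of 11 that fell, EXPA18 at -2.51, and 2 that rose (median -0.27, adjusted p = 0.104). Of 10 photosystem genes 6 fell and 0 rose (median -0.91, adjusted p = 0.0982). Vacuolar proteases had 1 of 5 that rose, BETA-VPE (3.09), and 1 that fell (median 0.03, adjusted p = 0.731). Gibberellin perception genes had 2 of 4 that rose and 1 that fell (median 0.37, mean -0.02, an upward test with adjusted p = 0.731), and 2 of 4 Aux/IAA genes fell (median -0.40, adjusted p = 0.156). For the 8 lists these counts were the same when adjusted over the list alone. Several smaller counts changed when 1 embryo array was left out. Photosystem falls numbered 3 without control replicate 1 or 2 or ABA replicate 3, and only 1 Aux/IAA gene fell whichever of the 6 arrays was left out. The fall of a pathogen response gene ended (0) without any of the 6 but control replicate 3. Without control replicate 2 or ABA replicate 2 only 1 gibberellin perception gene rose, and without control replicate 1 or ABA replicate 2 only 1 expansin. ICL was at 0.06 ± 0.13 (limma, adjusted p = 0.754). In endosperm it fell under ABA (-0.51 ± 0.13; limma, adjusted p = 0.00646), a call that ended with the median embryo ratio taken out (-0.38) and in a fit on the compared arrays alone (-0.51). In all 7342 probe sets were called, 3658 up and 3684 down.

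The largest falls under PAC in endosperm included those of protease genes and a pectin methylesterase gene. AOP3 (AT4G03050), a dioxygenase of glucosinolate side chains, rose by 3.91 ± 0.23 from a mean signal of 3.09 to 272 (limma, adjusted p = 6.46e-10). AT5G11420 rose by 3.02 ± 0.37 and AT3G25290 by 2.48 ± 0.20 (n = 3). The protease gene AT1G29080 (-5.18 ± 0.41), the subtilase gene AT5G59130 (-4.68 ± 0.18), the serine carboxypeptidase-like gene SCPL34 (-4.32 ± 0.33) and the pectin methylesterase gene AT3G10720 (-3.98 ± 0.18) fell.

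Xyloglucan endotransglucosylases fell in 4 of 7 cases under PAC in endosperm and 0 rose (5 fell when adjusted over the list alone). XTH18 (-4.02 ± 0.27), XTH33 (-2.55) and XTH16 (-2.47) were among them. Their median was -2.10 (limma camera, adjusted p = 3.55e-06), and this call held with an estimated correlation (adjusted p = 0.0278), the only one of the fixed lists in any comparison to do so. After the lowest or median embryo ratio was taken out 4 fell, with medians of -2.04 and -1.97. LEA genes had 3 of 7 that rose and 1 that fell (4 rose when adjusted over the list alone; median 1.09, adjusted p = 0.112). M17 rose by 2.60 ± 0.46 and M10 by 2.03. Beside this group stand the embryo ratios: with the lowest, 11%, taken out 3 members rose, 1 fell and the median was -0.22, with M17 (2.19) and M10 (1.26) still called. With the median ratio of 20%, beyond the cap, 1 rose, 1 fell, the median was -0.52, and the calls of M17 (1.59) and M10 (-1.50) ended. The cupin gene AT2G28490 rose by 2.70 as deposited and was called after neither step, with -1.17 after the latter. Of 433 rises of at least 2-fold 350 and 281 were still called.

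Among the other lists, pathogen response genes had 3 of 5 that rose and 1 that fell (median 1.04, adjusted p = 0.112), with PDF2.1 at 1.91 and 0 falls without endosperm control replicate 1, 2 or 3 or PAC replicate 3. Vacuolar proteases had 0 of 5 that rose and 2 that fell (3 when adjusted over the list alone), with a median of -0.65 (limma camera, adjusted p = 0.119). With the lowest embryo ratio taken out 2 fell, and with the median ratio 1. Of 4 gibberellin perception genes 2 rose and 1, SPT, fell (-1.24), for a list median of 0.51 (adjusted p = 0.434), with 1 rise without endosperm control replicate 1. Expansins had 1 of 11 that fell (median -0.09, adjusted p = 0.434), 0 without endosperm control replicate 1 and 2 without control replicate 3. No photosystem gene of 10 was called (median -0.58, adjusted p = 0.119), nor any of 4 Aux/IAA genes (median -0.24, adjusted p = 0.434). Without endosperm control replicate 3 there was 1 photosystem fall, and without control replicate 2 or PAC replicate 3 there was 1 Aux/IAA fall. PAC changed 4071 probe sets in endosperm, 2082 up and 1989 down. The count was 3223 with the lowest and 2426 with the median embryo ratio taken out, 2111 in a fit on these 6 arrays alone and 3027 without the third endosperm arrays.

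In embryo the maturation transcripts named under ABA were also higher under PAC than in the control. M17 rose by 7.09 ± 0.46 (limma, adjusted p = 3.54e-10), M10 by 6.32 ± 0.33 and PAP85 by 5.49 ± 0.45. The major latex protein-like genes AT4G23670 (-7.30 ± 0.37) and AT4G23680 (-6.79 ± 0.22) fell, as did AT2G45180 (-5.97 ± 0.60) and the pectate lyase gene AT5G48900 (-5.40 ± 0.26; n = 3).

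Among LEA genes in PAC-treated embryo 5 of 7 rose and 1 fell (median 3.37; limma camera, adjusted p = 0.0109; adjusted p = 0.188 with an estimated correlation). With the median endosperm ratio taken out this call ended as well (3.38, adjusted p = 0.0652). Of 5 pathogen response genes 4 rose (1 fell when adjusted over the list alone), with a median of 3.19 (adjusted p = 0.0066; adjusted p = 0.182 with an estimated correlation). Xyloglucan endotransglucosylases fell in 6 of 7 cases, XTH19 at -3.07 and XTH32 at -2.74 (median -1.87, adjusted p = 0.00488; adjusted p = 0.182 with an estimated correlation). Expansins had 5 of 11 that fell and 1 that rose, EXPA8 at -3.65 and EXPA18 at -2.54 (median -0.43, adjusted p = 0.0246; adjusted p = 0.187 with an estimated correlation). Photosystem genes had 5 of 10 that fell, PSAN at -3.89, and 0 that rose (median -1.34, adjusted p = 0.0331; adjusted p = 0.477 with an estimated correlation). This last call also ended without embryo control replicate 1 (median -1.20) or embryo PAC replicate 1 (-1.27), and with the lowest (-1.34, adjusted p = 0.0521) or median (-1.34, adjusted p = 0.0652) endosperm ratio taken out. Gibberellin perception genes had 3 of 4 that rose, among them the receptor gene GID1A (1.39), and 1 that fell, SPT (-1.67). Their median was 0.59 (limma camera, adjusted p = 0.456). With 1 array left out at most 2 rose, and only 1 without embryo control replicate 2 or PAC replicate 2. Of 4 Aux/IAA genes 2 fell (median -0.51, adjusted p = 0.0988), or 1 without embryo control replicate 1 or 3 or PAC replicate 3, and of 5 vacuolar proteases 1 rose and 1 fell (median 0.22, adjusted p = 0.573). The rise of 1 expansin was kept only without embryo PAC replicate 2, and ended (0) without any other of the 6 arrays. Other counts were the same when adjusted over the list alone. In all 8065 probe sets were called, 3977 up and 4088 down.

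**Figure D2:**
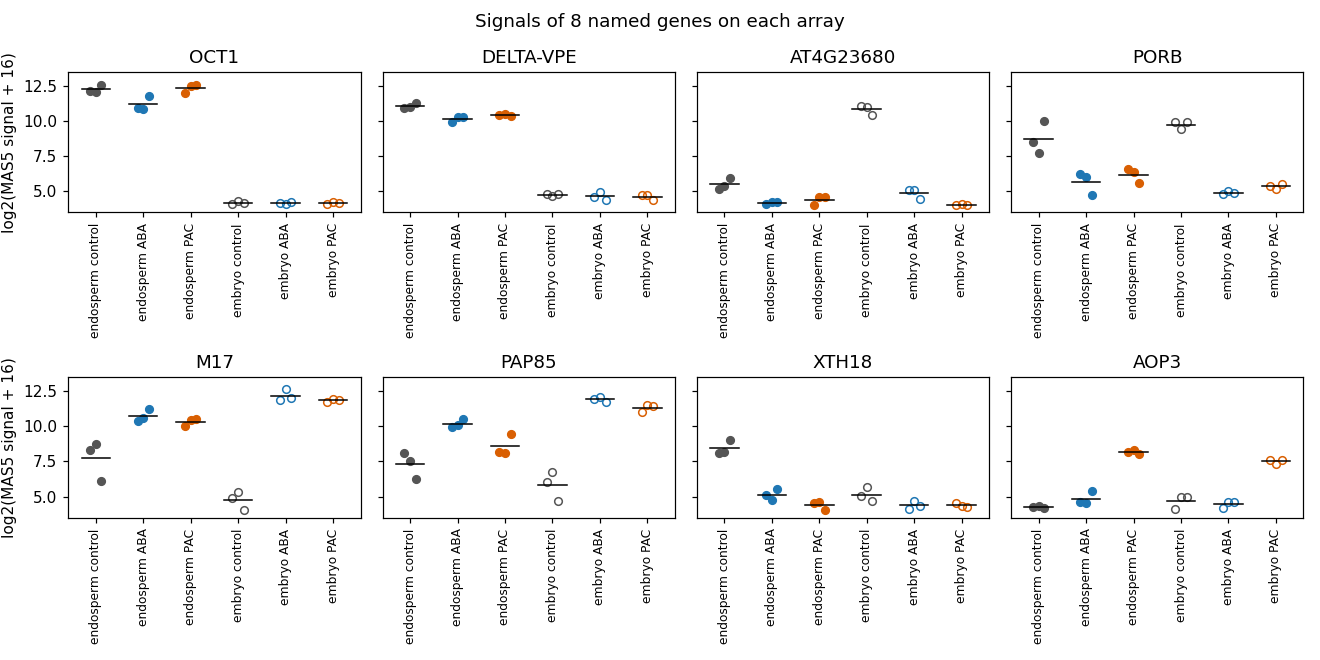
Signals of 8 named genes on each array as log2(MAS5 signal + 16) (y axis); each point is 1 array, filled for endosperm and open for embryo, and bars are means of 3 arrays. OCT1 and DELTA-VPE were bright in endosperm only, M17 and PAP85 rose in embryo under both compounds, and AOP3 rose under PAC in both tissues.

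Single members of shorter lists moved as follows. AIM1 of fatty acid beta-oxidation rose in embryo under ABA (0.92). EEL, a bZIP transcription factor gene, rose under ABA in endosperm (1.12) and embryo (1.51); the endosperm call stayed with the lowest embryo ratio taken out (0.87) and ended with the median (0.38). EIN3 of ethylene signalling rose in embryo under ABA (1.28) and PAC (1.48). OLEO3, an oleosin gene, rose under ABA in endosperm (2.03) and embryo (2.34), and its endosperm call stayed with the lowest embryo ratio taken out (1.72) and ended with the median (0.72).

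The effect of ABA differed between the tissues for 4368 probe sets, 2263 with a more positive and 2105 with a more negative effect in endosperm. AT1G29090 had the most negative difference (-6.84 ± 0.59; limma, adjusted p = 2.36e-07). M17 was at -4.44 ± 0.65, having risen in both tissues and by more in embryo. JAL22 (4.59 ± 0.31) and AT4G23680 (4.65 ± 0.31) fell mainly in embryo, where they had been bright. For PAC 4247 probe sets differed, 2305 more positive and 1942 more negative, including AT4G23680 (5.67 ± 0.31), AT1G29080 (-5.17 ± 0.58) and PAP85 (-4.23 ± 0.64). Pathogen response genes had 0 more positive and 3 more negative of 5 for ABA (median -1.98, adjusted p = 0.0239; adjusted p = 0.228 with an estimated correlation) and for PAC (median -2.15, adjusted p = 0.00553; adjusted p = 0.24 with an estimated correlation). LEA genes had 1 of 7 more positive and 4 more negative for PAC (5 when adjusted over the list alone; median -2.28, adjusted p = 0.033; adjusted p = 0.24 with an estimated correlation), a call that ended without endosperm PAC replicate 1 (median -2.40) or embryo PAC replicate 3 (-2.21). For ABA the LEA list was not called (median -0.70, adjusted p = 0.183).

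**Figure D3:**
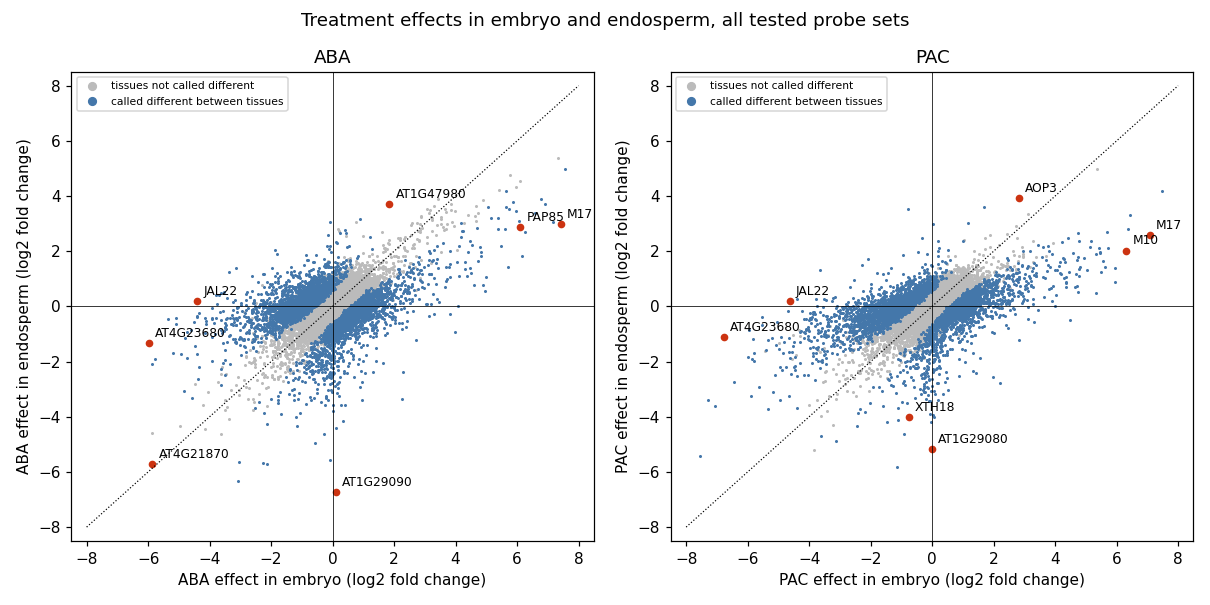
Treatment effect in endosperm (y axis) against that in embryo (x axis) as log2 fold changes of all 15819 tested probe sets, for ABA (left) and PAC (right). Blue points were called different between the tissues (4368 for ABA, 4247 for PAC), labelled red points are named genes, and the dotted line marks equal effects.

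ABA and PAC differed from each other in fewer probe sets than either did from the control, 9.87% of those tested in endosperm and 3.62% in embryo. In endosperm 1562 were called, 848 higher under ABA and 714 higher under PAC, and in embryo 572, with 374 and 198. A pair of genes with large differences in both tissues was chosen after their values were seen. AOP3 was lower under ABA than under PAC in endosperm (-3.31 ± 0.23; limma, adjusted p = 1.42e-08) and in embryo (-3.03 ± 0.23; limma, adjusted p = 7.07e-08). AT5G59130 was higher under ABA by 3.72 ± 0.18 in endosperm (limma, adjusted p = 1.11e-10) and 2.83 ± 0.18 in embryo. Among fixed list members, XTH16 was higher under ABA in endosperm (1.33) and embryo (1.18), calls that ended with the median ratio of the other tissue taken out (0.68 and 1.18) and stayed with the lowest (1.28 and 1.18). No fixed list was called between the compounds. Without the third endosperm arrays the endosperm count was 2620, and in a fit on the compared arrays alone it was 862. The embryo count fell to between 342 and 379 without embryo ABA replicate 1 (357) or 2 (373) or embryo PAC replicate 1 (342), 2 (357) or 3 (379), was 408 with the lowest and 274 with the median endosperm ratio taken out, and 937 in a fit on the compared arrays alone.

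Effects of ABA and PAC ran together across probe sets, which are not independent replicates. In embryo their Pearson correlation was 0.936 (Spearman 0.926), and in endosperm 0.759 (0.729). Both compounds were compared with the same 3 control arrays, and unchanged groups simulated against such controls gave 0.5 and 0.499. These simulations used independent noise with the same spread in every group. They left out the pairing by replicate number and the larger residual SDs in endosperm. The covariance was 0.903 against a simulated 0.0243 in embryo, a difference of 0.879, and 0.345 against 0.0243 in endosperm, a difference of 0.321. In embryo 3158 probe sets rose and 3277 fell with both compounds, where independent lists would share 920 and 952, and 4 and 7 were called in opposite directions. In endosperm 1336 rose and 1348 fell with both, against 327 and 288. With 3 control arrays no split into groups of at least 2 was possible, so part of the excess may come from the shared controls. Between the tissues, which share no arrays, the effects correlated at 0.496 for ABA (Spearman 0.412) and 0.546 for PAC (0.529). With the lowest ratio of the other tissue taken out these correlations were 0.455 and 0.477, and with the median ratio 0.334 and 0.331. ABA raised 1229 and lowered 1124 probe sets in both tissues, against 575 and 534 for independent lists, and for PAC these were 1268 and 1155 against 523 and 514.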

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

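The tests of carried-over RNA and of the third endosperm arrays were chosen after results were seen; the tests of the embryo and endosperm counts and the regroupings of arrays were planned beforehand.

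Effects that differed between the tissues form the group set apart here. For ABA 4368 probe sets differed, and for PAC 4247. The genes with a more positive ABA effect in endosperm were AT2G45180 (4.68), AT4G23680 (4.65), JAL22 (4.59), AT1G29670 (4.45) and AT1G04040 (4.06). Those with a more negative one were AT1G29090 (-6.84), AT1G07690 (-4.52), M17 (-4.44), AT2G34080 (-4.40) and AT2G32190 (-4.40), and the pathogen response list had a median of -1.98. For PAC the more positive genes were AT4G23680 (5.67), AT5G57760 (4.84), JAL22 (4.84), AT1G73120 (4.50) and AT5G01870 (4.33). The more negative were AT1G29080 (-5.17), M17 (-4.49), M10 (-4.29), AT2G32190 (-4.24) and PAP85 (-4.23), with list medians of -2.28 for LEA and dehydration proteins and -2.15 for pathogen response genes.

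In comparisons of 2 groups, arrays were regrouped in every way that keeps groups of 3. For the tissue differences of the effects, 100 regroupings of treatment within each tissue were used, the real one and others drawn at random. For these tissue differences 6 of 100 regroupings, the real one included, called as many probe sets, with a highest other count of 5222 for ABA and 8546 for PAC, so chance is not excluded by this count. All 5 other regroupings as large kept or mirrored the treatment labels of the embryo arrays and so still carry the embryo effect. In each of the 9 comparisons of 2 groups only the real grouping, 1 of 10, called as many. The highest other counts were 1, 0 and 0 for the tissues under control (real count 8858), ABA (3568) and PAC (4405). They were 5 and 0 for ABA in endosperm (4778) and embryo (7342), 1 and 0 for PAC in endosperm (4071) and embryo (8065), and 23 and 0 for ABA against PAC in endosperm (1562) and embryo (572). Each other split mixes arrays of both real groups, so real differences raise its spread and hold its count down. Low counts of the other splits therefore say little about the strength of the real one. With 10 splits a share cannot go under 0.1, too few for one under 0.05.

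Fewer probe sets differed between the tissues under ABA (3568) and PAC (4405) than in the control (8858). RNA carried from one tissue into samples of the other could do this if taking it out brought the counts to at least 80% of the control, 7086. With the lowest ratio between the tissues as the share, the counts were 4275 under ABA and 4825 under PAC with rescaling. Without rescaling they were 5088 and 5300, so all stayed under the bound. The same share was taken from each array of a group. Differences in carry-over between arrays thus stayed in the spread and could hold the counts down. For this reason the counts do not tell whether carry-over was the whole cause. The median of the 20 lowest ratios, used first and larger than the data allow, gave 5218 and 4973 with rescaling and 7377 and 6040 without, so only unscaled subtraction of that larger share passed the bound, under ABA. The rescaling and the smaller share were both chosen after counts had been seen, and carry-over may still account for part or all of the gap.

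The third endosperm arrays stood apart from the other 2 of their groups. RNA degradation should have given each of them the highest 3'/5' ratios of both GAPDH and actin, which held in 2 of the 3 groups, so degradation does not account for all 3. Less embryo RNA in these arrays would lower transcripts brighter in embryo, which were chosen in the arrays of another treatment. Over transcripts 10 times brighter in embryo the highest median was -0.04 (-0.0375, PAC), with -0.794 in ABA and no such probe sets for the control array. For the control and ABA arrays alone, over transcripts at least 4 times brighter, the highest was -0.41 (-0.411). These medians were -0.876 and -1.06 in the control array, -0.489 and -0.411 in ABA, and -0.0598 and -0.189 in PAC. Transcripts at least 4 times brighter in endosperm had 0.386 and 0.484, 0.412 and 0.483, and -0.0543 and -0.215. Brightness in embryo under one treatment need not hold under another. AT4G23680 had 2121 in embryo control replicate 1 and 0.31 in embryo PAC replicate 1. PAP85, bright in PAC embryo, had 260 in endosperm control replicate 1 and 51.1 in embryo control replicate 1. In the control and ABA arrays transcripts brighter in embryo were thus lower and those brighter in endosperm higher, unlike in the PAC array. Because brightness may change with treatment, these medians do not settle whether the arrays held less embryo RNA. A shared batch is not settled, since the lowest correlation of their deviations was 0.0194. The 25S rRNA signal was lower in all 3 than in the other endosperm arrays.

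More probe sets were called for ABA and PAC in embryo than in endosperm, with ratios of 1.54 and 1.98. If the third endosperm arrays caused this through the endosperm means, the lower ratio should approach 1 when the third arrays of all groups are left out, and it was 1.68. If the scaling between arrays caused it, quantile normalization should remove it, and the lower ratio was 1.53. Both values argue against these explanations. The larger residual SDs of the third endosperm arrays were not tested in this way. The main fit shares 1 spread between the tissues, so they raise SEs alike in both. For ABA the SD of the log2 fold changes across probe sets was 0.938 in embryo and 0.715 in endosperm. For PAC it was 1.03 and 0.636. The effects as measured were thus larger in embryo, and the cause of this was not tested.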

How the results depend on the processing

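The fits without the third endosperm arrays and with the median or lowest ratio of the other tissue subtracted were chosen after results were seen; all other alternatives were planned beforehand.

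With 1 array left out 7994 to 8540 probe sets were called for the tissues in the control, 6189 to 6726 for ABA and 7031 to 7437 for PAC in embryo, and 3305 to 4902 for ABA and 2847 to 3998 for PAC in endosperm.

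A fit on only the arrays compared called 2370 probe sets for ABA and 2111 for PAC in endosperm. In embryo it called 8115 for ABA and 9301 for PAC, so the gap between the tissues was wider than in the main fit. Endosperm counts thus fell and embryo counts rose where each comparison used only the spread of its own arrays. For ABA against PAC the fit on only the arrays compared called 862 in endosperm and 937 in embryo. Leaving out the third endosperm arrays gave 2620 for ABA against PAC in endosperm, and subtracting the median ratio of the other tissue gave 2426 for PAC in endosperm and 274 for ABA against PAC in embryo. With 1 array left out that last count ranged from 342 to 458.

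The correlation of ABA and PAC effects in endosperm was 0.604 without the third endosperm arrays and 0.622 with the median ratio subtracted. In embryo it was 0.915 at pseudocount 1 and 0.921 to 0.939 with 1 array left out. Between the tissues it was 0.334 for ABA with the median ratio subtracted, and for PAC 0.331 with the median and 0.477 with the lowest ratio subtracted and 0.507 without the third endosperm arrays.

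Subtracting the median ratio turned the direction of several endosperm effects. Under ABA these were PAP85 (-1.76), M17 (-0.50) and LTI30 (-1.73), and under PAC AT2G28490 (-1.17), PAP85 (-2.07), M10 (-1.50) and EXPA8 (0.0409). With the lowest ratio PAP85 under PAC turned (-1.70), as did the median of the LEA list under PAC (-0.22), which was not called before. The ratio taken out there, 11%, was above the lowest one at an embryo signal of at least 200, 9.23%. EXPA8 under PAC in endosperm ranged from -0.44 to 0.18 with 1 array left out, turning without endosperm PAC replicate 3 (0.18). Of the gene results 6193 stayed the same, 312 weakened and 9 turned, and of the list results 202 stayed called and 32 lost the call, among them the LEA list under ABA in endosperm with the median ratio subtracted, whose median turned (-0.27) while its test still pointed up.

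The replicate number as a block called 9007 probe sets for the tissues in the control, 5014 for ABA and 4318 for PAC in endosperm, and moved no count by more than 1.5-fold. It ended calls of PAP85 under PAC in endosperm, SLY1 under PAC in embryo and EXPB2 in the tissue difference of the PAC effect, none of them comparisons where numbers pair. Deviations of same-numbered arrays in those not paired correlated at -0.0553, 0.00859 and -0.145 for the tissues in the control, 0.153, 0.0641 and 0.104 under ABA, and 0.0929, 0.0856 and 0.00746 under PAC. They were 0.139, 0.144 and 0.0194 for PAC in endosperm, -0.054, 0.0179 and -0.146 for PAC in embryo, and -0.00859, 0.0732 and -0.129 for ABA against PAC in embryo. Of 3 arrays, those best with their own number were 1, 2, 2, 2, 0 and 1 in this order. The cause was not tested.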

Other observations

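Added gene families, defined by name before single-gene values were looked at, showed further changes. Tubulins, the subunits of microtubules, had 6 of 7 members that fell and 0 that rose under PAC in endosperm (median -0.86; limma camera, adjusted p = 0.00033; adjusted p = 0.089 with an estimated correlation). In embryo 5 of 7 fell and 1 rose under PAC (6 fell when adjusted over the list alone; median -1.19, adjusted p = 0.00969; adjusted p = 0.155 with an estimated correlation). Under ABA in endosperm they were higher than under PAC in 5 cases (median 0.63, adjusted p = 0.00112; adjusted p = 0.156 with an estimated correlation). Serine carboxypeptidase-like genes had 10 of 17 that fell and 1 that rose under PAC in embryo (median -0.84, adjusted p = 0.0114; adjusted p = 0.0882 with an estimated correlation). Glycosyl hydrolase family 9 genes, which include cellulases, fell in 4 of 6 cases under PAC in embryo (median -2.12, adjusted p = 0.02; adjusted p = 0.155 with an estimated correlation).

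Autophagy genes of the ATG family had 5 of 8 that rose under PAC in embryo and 0 that fell (6 rose when adjusted over the list alone; median 0.99; limma camera, adjusted p = 0.0283; adjusted p = 0.414 with an estimated correlation). Genes encoded in the plastid had 27 of 64 lower and 1 higher in control endosperm than in embryo (26 lower when adjusted over the list alone; median -0.71, adjusted p = 0.0166; adjusted p = 0.663 with an estimated correlation). They were also lower in endosperm under ABA, 15 of 64 with 1 higher (18 lower when adjusted over the list alone; median -0.65, adjusted p = 0.000196; adjusted p = 0.752 with an estimated correlation), and under PAC, 14 of 64 (median -0.69, adjusted p = 1.07e-05; adjusted p = 0.883 with an estimated correlation).

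Of the 2-fold rises in endosperm 202 of 657 under ABA (30.7%) and 132 of 433 under PAC (30.5%) ended above the embryo level. At a minimum embryo signal of 200 the median of the 20 lowest endosperm-to-embryo ratios was 2.76%, 19.3% and 13.3% for control, ABA and PAC.

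The labels give no measure of tissue purity, of germination at 24 hours or of the number of seeds per sample.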
